A study of Mus musculus with 17 samples.

How the data were processed

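RNA of liver and hippocampus was measured on a pair of mouse oligonucleotide array types, called chip A and chip B. The 17 arrays cover 5 liver RNAs on both chips, 3 hippocampus RNAs on both chips and 1 hippocampus RNA, of mice fed both oils, on chip B. No chip A array of that RNA was analysed here. Groups were taken from the array titles and descriptions. Per the labels, both tissues came from mice of the same diets.

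The authors deposited 1 intensity per probe set and array, as whole numbers that include negative values, which is what background subtraction leaves. The software, background method and scaling step that made the deposited intensities are not given in the sources used here. From the values themselves, the mean of each array after trimming the lowest and highest 2% lay between 148.1 and 150, so the arrays of a tissue were taken as already scaled to a common level and used as deposited. Control probe sets, 55 per chip, were left out of all tests and used only for the 3-prime to 5-prime ratios. For the chip B array of the hippocampus of mice fed fish oil no values of these probe sets were analysed here.

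Probe sets were named through the platform annotation supplied with the values. On chip A, 5541 of 6529 tested probe sets have 1 gene symbol, 197 several and 791 none, and on chip B the numbers are 2001, 27 and 4512 of 6540. Only probe sets with 1 symbol were named, and updating the symbols through gene identifiers changed 0 of them. A gene with several probe sets is represented by the brightest over the arrays of the tissue, and others are given where they disagree in sign.

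Intensities below a floor of 0.1 times the trimmed mean (15.0) were set to the floor, and log2 was taken. A gene at the floor on 1 side has only a bound, written as at least N-fold. Probe sets with a mean at or above the median of their chip and tissue were kept, 3265 and 3272 in liver. Signal over background, and not depth, limits the precision, as does the number of arrays.

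The liver was fitted with limma (3.58.1, in R 4.3.3) as 4 diet groups, with lmFit and eBayes with an intensity trend, separately per chip, and p-values of both chips were adjusted together by the Benjamini-Hochberg method. Only the control group is replicated, so the fit has 1 residual degree of freedom before moderation, with prior degrees of freedom of 2.17 on chip A and 2.05 on chip B, and each oil RNA is assumed to vary as the controls do. Standard errors are those of this fit. The contrasts were each oil diet against control, fungal oil against fish oil, and the interaction of the oils. The hippocampus has 1 RNA per diet and was described by log2 ratios to the control array, except for an additive limma fit of the 4 chip B arrays. Tissues were compared by a limma fit of tissue and diet after scaling every array to the same trimmed mean, with calls at an adjusted p under 0.05 and at least 2-fold. Bounds between tissues were taken from the group means of log2 values with the floor, not from the fit.

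Before the data were examined, 39 gene lists of pathways and cell type markers were fixed, of which 35 had at least 3 measured members in liver. List shifts in liver were tested by cameraPR with a preset correlation of 0.01 over 3515 genes, adjusted over 105 tests, and again by camera with an estimated correlation, which left 0 lists called for any diet. The estimated correlation rests on 1 residual degree of freedom, and in simulation that test recovered 0 of 20 shifted lists. It could hardly call any list, so its p-values, given beside the lists below, count neither for nor against them. With the preset correlation the genes serve as replicates, so the p-values of cameraPR hold for the RNAs measured and not for the diets. Members were also adjusted over the list alone. In the hippocampus each list's median was placed among 10000 random lists of the same size and matched brightness, which describes these arrays and is not a test of the diets.

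The rule for named genes was fixed at the same time: for each liver diet the 10 largest rises and 10 largest falls among called genes, filled up by genes at least 2-fold from each control and said not to pass, the 10 largest each way among probe sets at or above the 75th percentile of brightness in hippocampus, the 10 largest differences each way between tissues, and members of the lists. Alternatives fixed then were quantile normalization, 0.5 and 2.5 times the floor, no filter on dim probe sets, a bright subset at or above the 75th percentile, no intensity trend, an additive fit of the oils, leaving out each control, tissue without diet, and the mean over a gene's probe sets. Chip A alone and the hippocampus arrays against the mean of the others were added after seeing the data.

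Each fit was tested on simulated data with 200 changed probe sets. Simulated values were normally distributed and had no floor, and their spread, taken from the liver controls, depended only on brightness. In the real liver fit the spread also differed between probe sets of like brightness, with prior degrees of freedom of only 2.17 and 2.05. Recovery in the real data may therefore be lower than given here. The liver group fit recovered 37.3% of planted 2-fold, 74.6% of 4-fold and 86.4% of 8-fold changes among 6537 probe sets, and the bright-subset fit 74.6%, 98.5% and 98.5% among 3269, with 16 of 148 and 17 of 198 calls false. The additive liver fit recovered 50.7%, 82.1% and 92.4%, and the tissue fit 32.8%, 64.2% and 83.3%. Of 20 simulated lists shifted by -0.50, the preset correlation recovered 16 with 1 false call and the estimated correlation 0. Genes of the simulated lists varied independently, whereas genes of a pathway may vary together. The false call count therefore need not hold for the real lists. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.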

Results

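Expression was measured in liver and hippocampus of male NMRI mice, an outbred stock, kept 10 per cage and fed purified diets until they were killed on day 57 or 58. The control diet held neither test oil, and the others held 1.1% of a fungal oil rich in arachidonate, the precursor of many eicosanoids, 1.9% of a fish oil rich in docosahexaenoate, a major fatty acid of brain membranes, or both oils. Per the labels, 10 mice received each diet and 5 of them were selected for analysis. A cage of 10 could hold all mice of a diet, so cage may go with diet. Neither cage nor day of death can be told apart from diet in any oil contrast below. The liver gave 2 control RNAs and 1 RNA of each oil diet, and the hippocampus gave 1 RNA of each diet. RNA was hybridised to 2 oligonucleotide array types, called chip A and chip B here. For the hippocampus of mice fed both oils, chip B alone was analysed, which made 17 arrays. The labels do not say that the 2 liver control RNAs came from separate animals or pools, so the p-values of single genes in the liver diet groups measure only the spread between these 2 RNAs, which may be technical. The p-values of gene lists in liver set the genes of a list against the other genes of 1 oil RNA. However small, they measure no spread between RNAs of a diet and are not tests of the diets. Fits assuming additive oils take their error partly from the interaction of the oils, and in the hippocampus from it alone.

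The deposited intensities had been set to a common trimmed mean near 150, and array medians lay between 31 and 61. Between 15.3% and 18.6% of hippocampus values on chip A and between 31.6% and 34.4% of liver values on chip B were negative after background subtraction, so the dimmer genes have only a bound. On chip A the 2 liver controls correlated across probe sets with r = 0.954, and the standard deviation of their log2 difference was 0.50. Chip B was noisier, with r = 0.919 and a standard deviation of 0.80. Genes are not independent replicates in these correlations, and the number of arrays limits the precision of every value. The ratio of 3-prime to 5-prime Gapdh signal, which rises as RNA breaks down, was 0.840 to 0.947 in hippocampus and 1.89 to 3.26 in liver, and the same ratio for actin was 1.33 to 1.55 and 3.32 to 4.17.

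Fungal oil and the liver were compared first, to see how an arachidonate source altered hepatic transcripts. Transcripts for making fatty acids read lower. Acly, which supplies cytosolic acetyl-CoA from citrate, read 3118 and 3275 in the controls and 1568 with fungal oil, a log2 fold change of -1.03 (SE 0.08). Fatty acid synthase Fasn went from 5522 and 4906 to 2715 (-0.94, SE 0.14). The fatty acid elongase Elovl6 (-1.23, SE 0.15) and Gpam (-0.79, SE 0.10), which starts glycerolipid assembly, also fell. These 4 of the 12 measured lipogenesis genes passed when adjusted over the list alone, whereas the desaturase Scd1 (-0.16) and the lipogenic regulator Thrsp (0.25) did not. In the lipogenesis list 10 of 12 genes were below the control mean, the median was -0.31 and the list fell (camera, adjusted p = 1.01e-06, but adjusted p = 0.871 with an estimated correlation).

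Genes for burning fatty acids moved the other way with fungal oil. Of 24 measured genes of fatty acid oxidation and PPAR-alpha, the nuclear receptor that switches on lipid catabolism, 17 were above the control mean and the median was 0.19. That list rose (adjusted p = 7e-06, and adjusted p = 0.871 with an estimated correlation), although only Cyp4a10, a fatty acid omega-hydroxylase, rose when adjusted over the list alone (321 and 349 to 894, 1.42, SE 0.14). Drug-metabolising enzymes had a median of 0.19 and also rose as a list of 26 (adjusted p = 0.00899, and adjusted p = 0.871 with an estimated correlation), with 0 members passing over the list alone and a median of 0.08 or 0.11 against either control by itself and of 0.04 on chip A alone, an alternative chosen after seeing the data.

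Of 11 lipoprotein genes 6 lay below the control mean with fungal oil and 5 above, and 2 fell. Apoa4, an apolipoprotein of triglyceride-rich particles, fell from 1987 and 2034 to 781 (-1.36, SE 0.10), and Apom, which carries sphingolipids on high-density lipoprotein, fell by 0.52 on the log2 scale, both adjusted over the list alone. For the whole list the mean was -0.28 and the median only -0.05, and the list fell in the test (adjusted p = 0.0224, and adjusted p = 0.871 with an estimated correlation). The median was -0.08 against control 1 alone, -0.03 against control 2 alone and -0.26 on chip A alone. Fabp5, an intracellular fatty acid carrier, dropped from 3334 and 3137 to 593 (-2.45, SE 0.13), adjusted over a list of fatty acid binding and phospholipid genes drawn up for brain. All 5 measured cholesterol synthesis genes were below the control mean (median -0.34, adjusted p = 0.0313, and adjusted p = 0.871 with an estimated correlation), and Hmgcs1, the entry enzyme of the mevalonate pathway, fell (-0.61, SE 0.11) when adjusted over the list alone.

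The clock output gene Dbp, a transcription factor with a strong daily rhythm, rose with fungal oil from 176 and 162 to 581 (1.78, SE 0.14), adjusted over the list alone. The 5 clock genes had a median of 0.58, with 3 above the control mean and Nfil3 (-0.35) and Clock (-0.53) below it, and rose as a list (adjusted p = 0.00108, and adjusted p = 0.871 with an estimated correlation), but on chip A alone the median was 0.12. Genes of gluconeogenesis and amino acid breakdown rose as a list of 15 (median 0.18, adjusted p = 0.0168, and adjusted p = 0.871 with an estimated correlation), with no member passing over the list alone. That call was lost on chip A alone (adjusted p = 0.143). All 10 measured genes of macrophages and Kupffer cells, the resident macrophages of liver, were below the control mean (median -0.66, adjusted p = 0.00285, and adjusted p = 0.871 with an estimated correlation). The most abundant of them, the lysozyme gene Lyz2, read 472 and 376 in controls and 262 with fungal oil (-0.69), and the Kupffer cell gene Cd5l read 224 and 228 against 147 (-0.62), neither passing alone. Hepatocyte markers had a median of -0.01 (adjusted p = 0.939), and blood cell genes of -0.19 (adjusted p = 0.276), among which the erythroid haem synthesis gene Alas2 fell (-0.91, SE 0.14) over its list alone. The Gapdh ratio was 2.48 and 2.51 on the fungal-oil arrays, against 1.91 to 2.23 in controls, and the actin ratio 3.87 and 4.17 against 3.38 to 3.94.

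Over all 6537 liver probe sets kept, limma called 0 for fungal oil (lowest adjusted p = 0.415), with 599 at an unadjusted p under 0.05 where chance gives 327. A planned stricter filter, which kept a bright subset with means at or above the 75th percentile of each chip (3269 probe sets), called 26, 7 higher and 19 lower, of which 9 have no single gene name, and a fit assuming additive oils called 5. In this subset, simulated groups without any change gave 5.36 calls per diet on average, so some bright-subset calls of each diet may be false. The bright-subset calls, named after their values were seen, included Alas1, the rate-limiting enzyme of haem synthesis in liver (1299 and 1177 to 4573, 1.89, adjusted p = 0.0129), and the uridine phosphorylase Upp2 (806 and 812 to 2044, 1.34, adjusted p = 0.0182). They also included falls of the nuclear RNA Neat1 (-1.66, adjusted p = 0.0150), the collagen-modifying Plod3 (-2.30) and Emc10 (-2.45), a subunit of a membrane insertion complex, together with a rise of Errfi1, an inhibitor of EGF receptor signalling (0.87). The additive fit called rises of Upp2 (1.35) and Dbp (1.92) and a fall of Acly (-1.01), and gave Cyp4a10 0.54 and Neat1 -0.68, since it assumes that each oil does as much with the other oil as without it.

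Most genes with the largest nominal folds were dim. Among the 20 named by the fixed rule for fungal oil, the median mean intensity was 65.4, 13 had one side at the floor and 0 passed. S100a13, a small calcium-binding protein, read 21 and 84 in the controls and 473 with fungal oil, and the membrane protease Adam15 read 151 and 182 against a value below the floor, at least 11.1-fold lower.

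Genes of fatty acid oxidation were higher with fish oil in the liver. Cyp4a10 rose from 321 and 349 to 1566 (2.23, SE 0.14), and its relative Cyp4a14 rose from below the floor in both controls to 385, at least 25.7-fold higher. Cpt2, of the mitochondrial carnitine shuttle, went from 408 and 428 to 791 (0.92, SE 0.11), and Ech1, which handles unsaturated fatty acids, from 1226 and 1252 to 2031 (0.71, SE 0.08). Cd36, a fatty acid uptake receptor, rose from 280 and 213 to 591 (1.28, SE 0.27). Of the 24 genes 23 were above the control mean, 9 rose when adjusted over the list alone and 0 fell. The list's median was 0.42 and it rose (adjusted p = 1.31e-16, and adjusted p = 0.871 with an estimated correlation). A fit assuming additive oils gave smaller fish oil effects, 1.35 for Cyp4a10 and 0.56 for Cd36.

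Drug-metabolising enzymes were higher too, with 23 of 26 above the control mean, 6 rising over the list alone and a median of 0.33 (adjusted p = 4.69e-09, and adjusted p = 0.871 with an estimated correlation). Cyp2e1, a very abundant cytochrome P450, read 9172 and 9171 in controls and 13101 with fish oil (0.51, SE 0.05), the glutathione transferase Gstp1 rose by 0.52, and Cyp3a11, a broad drug oxidase, read 4935 and 4618 against 8429 (0.82, SE 0.13). Quantile normalization reduced the largest of these signals to 0.12 for Cyp2e1, 0.10 for Gstp1 and 0.03 for the liver fatty acid carrier Fabp1, which had risen by 0.41, and the list's median to 0.16, but left Cyp4a10 at 2.19 and Cd36 at 1.27.

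Of the lipogenesis genes, 2 fell with fish oil and 0 rose. Acly fell to 1754 (-0.87, SE 0.08) and Pgd, of the pentose phosphate pathway, from 139 and 135 to below the floor, at least 9.13-fold lower, both adjusted over the list alone. Fasn (-0.34), Elovl6 (-0.62), Gpam (-0.26) and Scd1 (-0.04) did not pass. Again 10 of 12 lipogenesis genes were below the control mean (median -0.26, adjusted p = 0.00212, and adjusted p = 0.871 with an estimated correlation), and the median was -0.15 against control 1 alone and -0.16 with the mean over all probe sets of a gene. Apoa4 fell to 629 (-1.68, SE 0.10), Apoc2, the cofactor of lipoprotein lipase, to 2143 (-0.58, SE 0.11) and Apom by 0.46 on the log2 scale. The lipoprotein list fell, with a mean of -0.27 and a median of -0.08 (adjusted p = 0.0140, and adjusted p = 0.871 with an estimated correlation), which was -0.05 against control 1 alone and -0.27 on chip A alone. Fabp5 fell to 384, 8.42-fold lower (-3.07, SE 0.13). Its list of 9 had a median of 0.04 and a mean near 0 (-0.00) but fell in the test (adjusted p = 0.0203, and adjusted p = 0.916 with an estimated correlation). Fabp5 was the 1 member that passed over the list alone. The median was 0.10 against control 1 alone and -0.09 against control 2 alone. The call was lost with the mean over all probe sets of a gene (median 0.34, adjusted p = 0.0714), and on chip A alone, where no Fabp5 probe set was kept, the test turned direction (adjusted p = 0.636).

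In the same fish-oil RNA, 8 of the 10 macrophage and Kupffer genes were below the control mean (median -0.70, adjusted p = 0.0202, and adjusted p = 0.871 with an estimated correlation). Lyz2 read 502 (0.25), Cd5l 127 (-0.83) and the Kupffer lectin Clec4f 180 and 254 against 90 (-1.25), none passing over the list alone, and the call was lost on chip A alone (median -0.46, adjusted p = 0.0915). Gluconeogenesis and amino acid genes had a median of 0.10 and rose as a list (adjusted p = 0.0354, and adjusted p = 0.871 with an estimated correlation), a call lost under quantile normalization (median 0.02, adjusted p = 0.261). The median was 0.08 against control 1 alone and 0.15 against control 2 alone. Of 3 oligodendrocyte and myelin genes measured in liver, Cnp, an enzyme of myelin, fell from 100 and 112 to below the floor, and the list fell (median -0.76, adjusted p = 0.0354, and adjusted p = 0.871 with an estimated correlation), a call also lost under quantile normalization (adjusted p = 0.0635). Hepatocyte markers had a median of 0.22 (adjusted p = 0.467) and blood cell genes 0.33 (adjusted p = 0.865), although Alas2 fell (-0.76, SE 0.14) over its list alone. On chip B the Gapdh ratio of the fish-oil RNA was 3.26, the highest of all arrays, while on chip A it was 1.95, between the chip A controls. The actin ratios of that RNA were 3.49 on chip A and 3.33 on chip B, the latter below both chip B controls (3.71 and 3.38).

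For fish oil limma called 0 of 6537 (lowest adjusted p = 0.375), with 724 at an unadjusted p under 0.05, and the additive fit called 0. The bright subset gave 39 calls, 16 higher and 23 lower, 15 without a single gene name. Beside Fabp5, Apoa4, Acly and Cyp4a10 these included falls of Neat1 (1218 and 1269 to 384, -1.69, adjusted p = 0.0117), the water channel Aqp8 (741 and 815 to 364, -1.09, adjusted p = 0.0441) and the gut-type surface protein Lypd8 (-2.36), and a rise of Retsat, which saturates retinol (1.03, adjusted p = 0.0403). A dimmer probe set of Retsat read the other way (-0.69), and a dimmer one of Lypd8 read -0.11. These names were chosen after their values were seen. Of the 20 genes named by the fixed rule, 12 had a mean intensity under 100 and 0 passed.

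**Figure D1:**
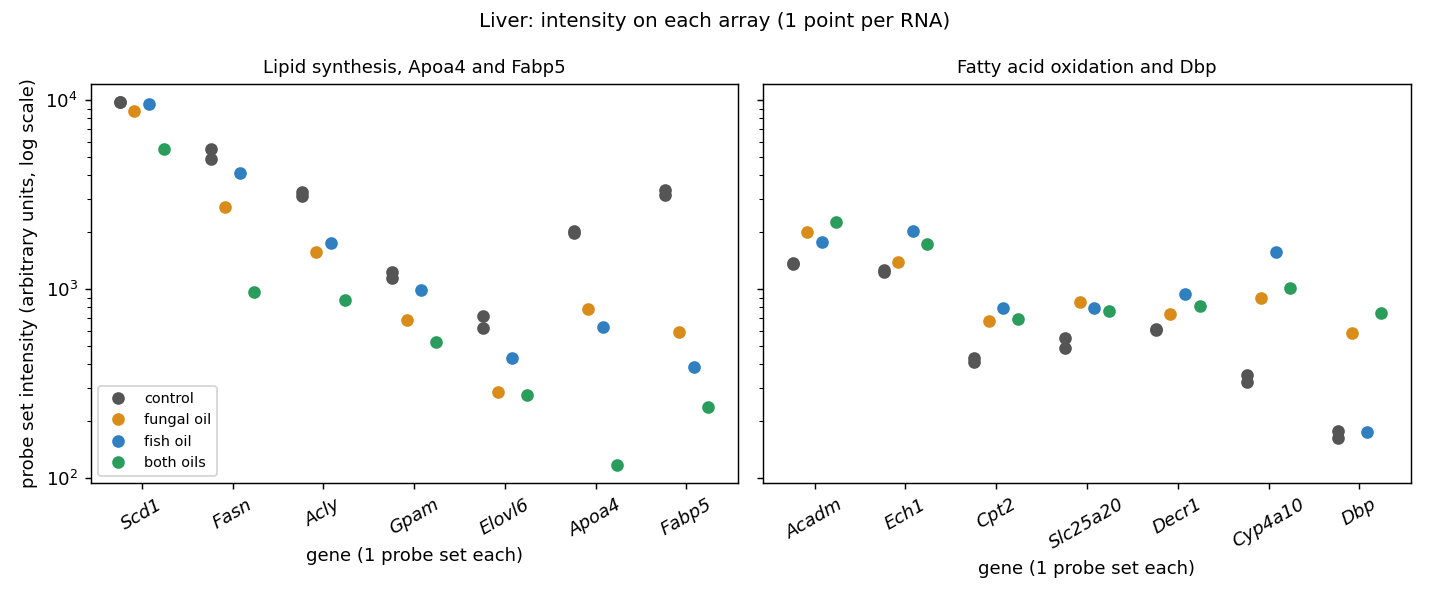
Liver intensities of selected genes on a log axis, with the 2 control RNAs and the single RNA of each oil diet as separate points. Apoa4 lay at 1987 and 2034 in the controls and at 117 with both oils, and Dbp was higher in the diets with fungal oil.

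With both oils together, lipogenic transcripts were at their lowest among the liver RNAs. Fasn went from 5522 and 4906 to 966 (-2.43, SE 0.14), Acly to 878 (-1.86, SE 0.08), Elovl6 to 274 (-1.28, SE 0.15) and Gpam to 526 (-1.17, SE 0.10). The very abundant desaturase Scd1 went from 9754 and 9811 to 5541 (-0.82, SE 0.05), and Thrsp from 2444 and 2518 to 1505 (-0.72, SE 0.11). Of 12 lipogenesis genes 11 were below the control mean, 9 fell when adjusted over the list alone and 0 rose. The median was -0.77 against a difference of 0.03 between the controls, and the list fell (adjusted p = 1.56e-30, and adjusted p = 0.871 with an estimated correlation).

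Apoa4 fell 17.2-fold with both oils, to 117 (-4.10, SE 0.10), the lowest adjusted p of the liver fit (0.114). Apoc2 fell to 2005 (-0.67, SE 0.11), and the phospholipid transfer protein Pltp, dim at 86 and 92 in controls, fell to 16. The 11 lipoprotein genes fell in the test and in the mean (-0.65), while their median was 0.06 (adjusted p = 7.58e-09, and adjusted p = 0.871 with an estimated correlation). The very abundant members Apoa2 (0.09) and Apoe (0.06, with -0.29 at another probe set) did not pass. Against control 1 alone the list's median was -0.01, against control 2 alone 0.10, under quantile normalization 0.03 and on chip A alone -0.11. Fabp5 fell 13.6-fold, to 238 (-3.76, SE 0.13). The fatty acid binding list fell (median -0.06, mean -0.79, adjusted p = 6.87e-06, and adjusted p = 0.871 with an estimated correlation), with Fabp5 and Pltp as the members that passed over the list alone, and the call was lost on chip A alone (adjusted p = 0.194). Its median was 0 against control 1 alone, -0.10 against control 2 alone and -0.02 under quantile normalization. Hmgcs1 fell (-0.76, SE 0.11) over its list alone, while the cholesterol synthesis list did not pass (median 0.02, adjusted p = 0.557).

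Oxidation genes were also higher with both oils, in 21 of 24 (median 0.39, adjusted p = 2.8e-07, and adjusted p = 0.871 with an estimated correlation), and 4 rose over the list alone. These were Cyp4a10 (1010, 1.59, SE 0.14), Cpt2 (0.72), Ech1 (0.48) and the medium-chain acyl-CoA dehydrogenase Acadm (0.73, SE 0.11). Dbp rose to 747 (2.15, SE 0.14) and Bhlhe40, a clock repressor, to 440 (0.90, SE 0.18), while Nfil3 (-0.90) and Clock (-1.05) read lower without passing, and the clock list rose (3 of 5 above the control mean, median 0.24, adjusted p = 0.0135, and adjusted p = 0.871 with an estimated correlation), although on chip A alone its median was -0.33. Drug-metabolising enzymes (median 0.21, adjusted p = 0.0793), the bile acid and sterol list (median 0.48, adjusted p = 0.129) and the gluconeogenesis list (median -0.01, adjusted p = 0.865) did not pass. G6pc, the last enzyme of glucose release, read 969 and 1160 in controls and 553 with both oils (-0.94), without passing. Macrophage and Kupffer genes had a median of -0.16 (adjusted p = 0.252), hepatocyte markers of -0.01 (adjusted p = 0.725) and blood cell genes of -0.58 (adjusted p = 0.146), where Hbb-b2, a beta-globin gene, fell (-0.85, SE 0.19) over the list alone. The Gapdh ratios were 1.89 and 1.92 and the actin ratios 3.51 and 3.32.

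Over all 6537 probe sets limma called 0 for both oils, with 647 at an unadjusted p under 0.05, against 37 in the bright subset (10 higher, 27 lower, 12 unnamed) and 16 with the additive fit (5 higher, 11 lower). Named after their values were seen, the bright-subset calls included Fasn (adjusted p = 0.00283), Scd1 (adjusted p = 0.00696), the stress-responsive transcription factor Atf5 (875 and 864 to 281, -1.63, adjusted p = 0.00876), Aqp8 (-1.83), the polyunsaturated fatty acid elongase Elovl2 (-0.83) and the rises of Alas1 (1.44, adjusted p = 0.0138), Upp2 (1.14), Cyp4a31 (1.63) and the ubiquitin-conjugating enzyme Ube2s (1.52). The additive fit also called Apoa4, Fabp5, Acly, Atf5, Dbp, Aqp8, Upp2, Fasn, Gpam and Ube2s. Among the 20 genes of the fixed rule 14 had a mean intensity under 100, such as the keratin Krt13, at least 8.94-fold higher, and 0 passed. Brighter members were the mitochondrial ribosomal protein gene Mrpl23 (251 and 241 to 15, about the floor) and the interferon-induced Ifi47, which read 164 and 277 in controls and below the floor with both oils.

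**Figure D2:**
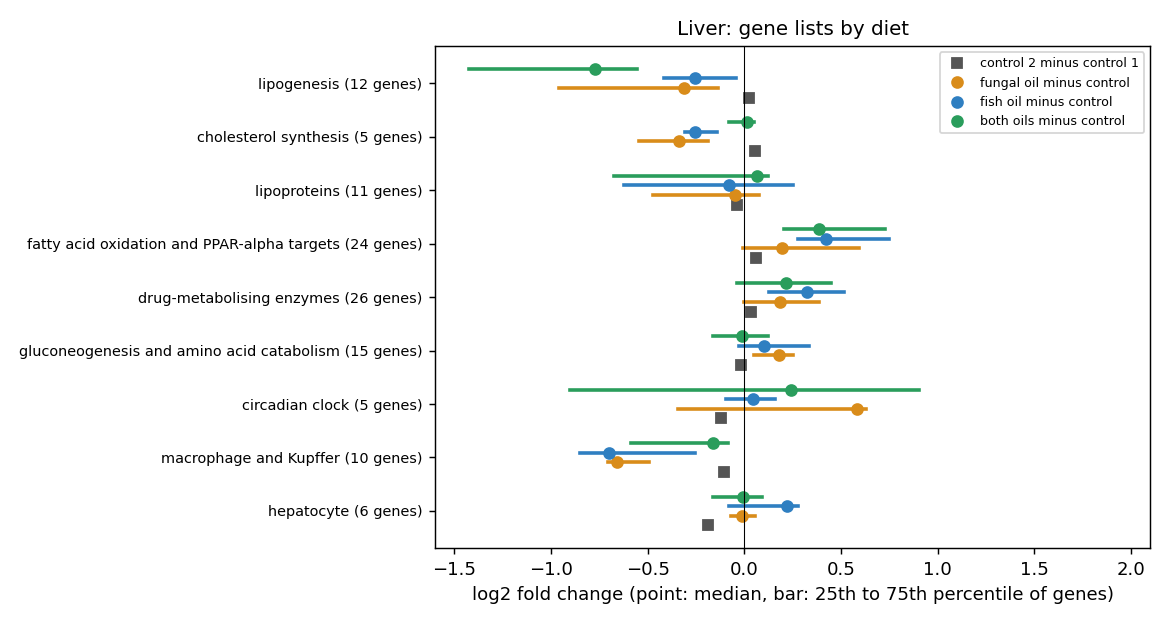
Median log2 fold change of selected fixed gene lists in liver, not all 35 tested, by diet, with control 2 against control 1 as the measure of spread. The lipogenesis list lay at -0.31, -0.26 and -0.77 with fungal oil, fish oil and both oils, and the oxidation list at 0.19, 0.42 and 0.39.

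The single oils were then compared with each other. Upp2 (1.57), Dbp (1.74) and Alas1 (1.01) were higher with fungal oil, and Cd36 (-1.41) with fish oil. limma called 0 of 6537 for this difference (adjusted p = 0.528 for each of these genes), with 588 at an unadjusted p under 0.05. In the bright subset 7 passed, of which 4 have a gene name: Upp2 and Lypd8 (2.33) were higher with fungal oil, and Plod3 (-2.46) and Emc10 (-2.34) with fish oil. The interaction asked whether both oils did more than the sum of each. Its log2 value was -1.15 for Fasn, -1.06 for Apoa4, -1.80 for G6pc, -2.05 for Cyp4a10, 2.27 for Neat1 and 1.76 for Fabp5, each at an adjusted p of 0.529, and 0.03 for Acly (adjusted p = 0.944). limma called 0 interactions, with 607 at an unadjusted p under 0.05, and 1 unnamed probe set in the bright subset. The steeper fall of Fasn and Apoa4 with both oils was therefore not shown to exceed the sum of the single oils.

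Calls overlapped between diets. Of the bright-subset calls, 10 were shared in the same direction by fungal and fish oil, 14 by fungal oil and both oils, and 12 by fish oil and both oils, where independent lists would share 0.310, 0.294 and 0.441. All 3 diets shared 9, of which 6 have a gene name: Fabp5, Apoa4, Acly, Aqp8 and Neat1 were lower and Cyp4a10 was higher in each. The diets share their controls, which alone produces likeness. Fold changes of fungal and fish oil correlated across probe sets at 0.386 where simulated unchanged groups gave 0.334, with a covariance of 0.163 against 0.112, and the other pairs gave correlations of 0.362 and 0.378 and covariances of 0.153 and 0.174. With a different single control for each diet the correlations were 0.0542 to 0.120, and 0.203 to 0.299 in the bright subset. There, unchanged groups simulated with shared controls and the fitted variances shared on average 0.900, 0.810 and 0.770 calls, and at an unadjusted p under 0.05 the pairs shared 154, 188 and 186 probe sets in the same direction against 25.9, 26.3 and 26.1 in simulation. Each simulated diet had 5.36 calls on average although nothing was changed. The simulated oil RNAs varied only by the fitted variances, which rest on the control RNAs, so a wider spread between oil RNAs is not covered.

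At least 2-fold from the control mean lay 631 liver probe sets with fungal oil, 719 with fish oil and 700 with both oils. Control 2 differed from control 1 by as much at 687. Against control 1 and control 2 singly, the like comparison, the counts were 808 and 737 with fungal oil, 859 and 869 with fish oil and 842 and 818 with both oils, and no test was made of these differences. In the bright subset the single controls gave 135 and 104, 143 and 131, and 156 and 133, against 72 between the controls.

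In the hippocampus each diet was 1 RNA, so there is no replicate check and no p-value for single arrays. Several genes of connective tissue and vessel walls read higher in every oil RNA than in the control RNA. Decorin, Dcn, a matrix proteoglycan, read 138 in the control, 511 with fungal oil, 351 with fish oil and 631 with both oils. The smooth muscle actin Acta2 read 112 against 598, 240 and 298, the secreted matrix regulator Ccn3 144 against 408, 304 and 504, and fibronectin Fn1 34 against 126, 98 and 136. The intermediate filament gene Vim read 299 against 529, 388 and 478. The median log2 ratio of the stellate cell and connective tissue list was 0.92 with fungal oil (8 of 8 genes higher), 0.31 with fish oil (7 of 8) and 1.14 with both oils (7 of 7 on chip B), at the 100th, 99.8th and 100th percentile of 10000 random lists of matched brightness. Endothelial markers had medians of 0.50 (98.2th percentile, 3 of 5 higher), -0.09 (34.2th percentile, 2 of 5) and 0.58 (93.9th percentile, 2 of 3). All rest on 1 control array: against the mean of the other hippocampus arrays, a reference chosen after seeing the data, the connective tissue medians were 0.52, -0.10 and 0.28.

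Ptgds, the prostaglandin D synthase abundant in meninges and choroid plexus, read 624 in the control, 3118 with fungal oil and 1843 with fish oil. Choroid plexus genes were higher with fungal oil (median 0.76, 99.99th percentile) but not with fish oil (-0.16, 14.1th percentile). Igf2 read 353 against 805 and 415, and transthyretin, Ttr, 304 against 490 and 157. Blood cell genes had a median of 0.36 with fungal oil (99.6th percentile), 0.13 with fish oil and 0.27 with both oils, while hippocampal neuron markers lay at -0.07 and -0.08 with the single oils. Astrocyte genes had medians of 0.08, -0.11 and -0.22.

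Glutamate receptor and transport genes had medians of 0.02, -0.06 and -0.21 with fungal oil, fish oil and both oils, and synaptic vesicle genes of 0.01, 0.02 and -0.15. Receptors for monoamines and acetylcholine had medians of 0.26 (98.1th percentile), 0.02 and 0.19, and potassium and other voltage-gated channels of 0.18 (98.1th percentile), 0.03 and -0.13. Genes of neurotrophins and plasticity lay at 0.03, -0.01 and -0.20 (5.82th percentile with both oils), and genes of the GABA system at -0.02, 0.08 and 0.08. Ribosomal protein genes had medians of -0.12 (0.07th percentile) and -0.06 (0.20th percentile) with the single oils and -0.10 (6.67th percentile) with both, and against the mean of the other arrays of -0.04 and -0.03 with the single oils. Somatostatin, Sst, a peptide of inhibitory interneurons, read 907 in the control and 1602, 1590 and 1930 in the oil RNAs. Dgat2, which makes triglyceride, read 542 against 280, 284 and 275, and Ifitm10 387 against 145 and 134 with the single oils.

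Among genes in none of the fixed lists, fish oil had lower Timp2, a metalloproteinase inhibitor (283 to 90), and Notch1, a receptor of cell fate decisions (265 to 88), and higher Id1, an inhibitor of differentiation (344, a log2 ratio of 1.22, and 0.69 with both oils). These values come from chip B, where the fish-oil array correlated least with the other hippocampus arrays (r = 0.917 to 0.929, against 0.941 to 0.947 among those). On chip B it had 293 probe sets at least 2-fold from the control, against 218 with fungal oil and 201 with both oils. Noise of that array cannot be told apart from an effect of fish oil. Both oils had lower Smarca4, a chromatin remodelling ATPase (466 to 141), Rcan1, an inhibitor of calcineurin (304 to 130, and 138 with fish oil) and Cd81, a tetraspanin (3812 to 2276). The histone reader Kmt2e read 75 against 280 and 270, the gamma-tubulin Tubg2 79 against 209 and 309 and the initiation factor gene Eif1b 424 against 1243 and 1336 with the single oils, although another probe set of Eif1b moved the other way. At least 2-fold from the control lay 344 of 6538 probe sets with fungal oil, 381 with fish oil and 201 of 3273 with both oils. An additive limma fit of chip B called 0 for either oil. At an unadjusted p under 0.05 it had 115 and 91, where chance gives 164. In simulation the fungal-oil fit recovered 0% of planted 8-fold changes, but with a spread taken from the liver controls. That figure may not hold for hippocampus arrays, whose spread between RNAs of 1 diet is unknown. With 1 residual degree of freedom the fit excludes little.

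**Figure D3:**
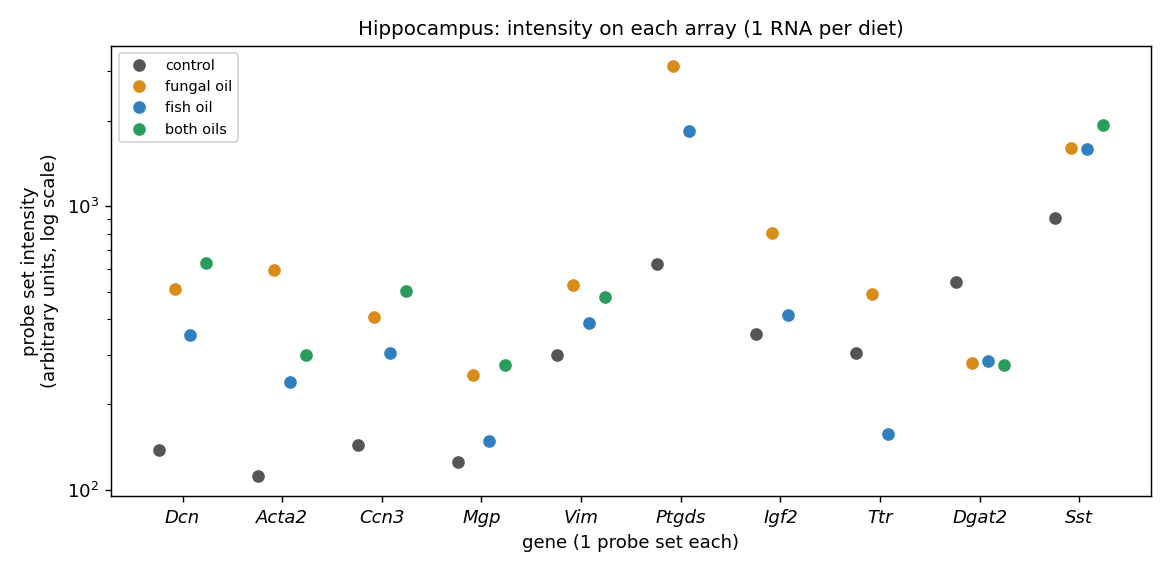
Hippocampus intensities of selected genes on a log axis, 1 point per diet. Dcn and Acta2 lay above the control (138 and 112) in every oil RNA, while Dgat2 lay below it; genes on chip A have no value for both oils.

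Liver and hippocampus were compared across diets as a check of tissue identity. Of 6535 probe sets, limma called 3313 at an adjusted p under 0.05 and at least 2-fold, 1248 higher in liver and 2065 in hippocampus. Quantile normalization gave 1516 and 1703, and it moved the median of all probe sets from -0.31 to -0.07. In liver Cyp2e1 read 9911 ± 1805 (SD, n = 5) and was below the floor in hippocampus, at least 653-fold higher. The fatty acid carrier Fabp1 was at least 549-fold higher and the plasma glycoprotein gene Apoh at least 650.2-fold. Albumin, Alb, read 12516 ± 1136 (SD, n = 5) in liver against 13.9 ± 35.7 (SD, n = 4), a mean below the floor. In hippocampus Basp1, a growth-cone protein, read 5313 ± 490 (SD, n = 4), at least 354-fold higher, and the neuronal surface protein Thy1 at least 282-fold. All 14 acute phase genes, all 9 bile acid and sterol genes and 21 of 23 oxidation genes were higher in liver, and 12 of 14 synaptic vesicle genes, 8 of 9 glutamate genes and 6 of 7 myelin genes in hippocampus. Of the connective tissue list 3 of 9 were higher in liver and 3 in hippocampus, and of the macrophage list 2 and 3 of 10. Ribosomal protein genes differed in 4 of 35, and 26 of 31 oxidative phosphorylation genes were not called. Tissue goes with a tag in the array titles and with the Gapdh ratio, which cannot be told apart from it.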

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

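All tests in this part were chosen only after the result was seen, except those of meningeal and vessel markers and of other splits of the RNAs. Quantile normalization was itself an alternative fixed beforehand, but its use here to judge scaling of the control array was chosen afterwards.

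Of 49 named genes measured in both tissues, 10 lay on opposite sides of the control in every oil RNA of liver and of hippocampus where they were measured. The mean over the diets was itself not tested. In hippocampus only Acadm, Alas2 and Dgat2 were measured with both oils. For the other genes the hippocampus mean covers the single oils alone, while the liver mean covers all oil diets. As the liver mean minus the hippocampus mean over the oil diets, they were Acadm at 0.64, Alas2 at -0.91, Dgat2 at 1.14, Ech1 at 0.54, Errfi1 at 0.71, Hmgcs1 at -0.93, Kmt2e at -2.53, Pgd at -2.71, Pltp at -1.94 and Ube2s at 1.70. Hmgcs1 averaged -0.54 in liver and 0.39 in hippocampus, and Dgat2 0.19 and -0.95. Some hippocampus means lay close to the control, such as Errfi1 at -0.040, Ech1 at -0.085 and Acadm at -0.085. Among all 2814 genes measured in both tissues 233 (8.28%) showed such opposition. A limma test of tissue by diet called 0 of 6535 probe sets for fungal oil and for fish oil and 0 of 3270 for both oils, with 741, 831 and 354 at an unadjusted p under 0.05. It included 23 tests of the 10 genes. These genes were picked for that opposition in the same arrays, so small unadjusted p-values were bound to follow and nothing is drawn from them.

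In the control probe sets, the Gapdh 3-prime to 5-prime ratio of the fish-oil liver RNA on chip B was 3.26, above the highest control liver value of 2.23, while the same RNA gave 1.95 on chip A, and its actin ratio on chip B was 3.33, below both controls (3.71 and 3.38).

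Connective tissue genes were higher in every hippocampus oil array than in the control array, with a lowest list median of 0.31. Quantile normalization moved 6513, 6512 and 3266 probe sets, but with a 95th percentile of the shift of only 0.124, 0.0661 and 0.108 on the log2 scale. It left the list's medians at 0.91, 0.28 and 1.14, at the 99.7th percentile or above of random lists of matched brightness. The arrays were thus already alike in distribution, which argues only against an array-wide difference of scale as the whole cause. Shifts this small could not have removed the medians, so the unchanged medians add little. Choroid plexus in the dissected piece may be a source and stays open, with Ttr at 0.69 and the choroid plexus list at 0.76 with fungal oil, but at -0.95 and -0.16 with fish oil. More meninges or vessels in the oil pieces may be a source and stays open: 28 markers not looked at before (14 with both oils; 23, 23 and 11 also measured in liver) had medians of 0.15, 0.13 and 0.24, with 19, 17 and 9 above the control, at percentiles from 96.4 to 98.6, and the 7 most abundant moved apart with fungal oil, where Gjb6 (379 to 388), Timp3 (301 to 469) and Vtn (164 to 324) were higher and Col18a1 (505 to 459), Col5a1 (368 to 307), Lgals3 (250 to 139) and Igfbp6 (209 to 140) lower, while with fish oil all 7 were higher. An effect of the oils cannot be told apart from a low control, since there was only 1 hippocampus control RNA.

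Dbp was higher in both liver RNAs of diets with fungal oil and near the control with fish oil alone. A difference in time of death between cages may explain it, since Dbp in the hippocampus of mice fed fungal oil was also higher (111 to 206, 0.89) and with fish oil lower (-0.40), only just over the bound of 0.5 times the liver rise. Per1 went with Dbp in hippocampus (0.82 and 0.02), while Bhlhe40 did not (0.03) and Clock read -0.16 and 0.01. In liver Per1 did not follow Dbp, at 0.58 with fungal oil, 0.32 with fish oil and 0.24 with both oils. The 2 liver controls differed by 0.12 against a lower rise of 1.78, which leaves the spread between RNAs of a diet open, since the labels do not say that these controls are separate animals or pools. An effect of fungal oil on Dbp stays open and untested apart from these.

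Lipogenesis genes were lowest in the liver RNA of the mice fed both oils, with a median of -0.77. Fewer hepatocytes in the piece are argued against, since the hepatocyte markers had a median of -0.00847. A longer fast could lower these genes and stays open, because the fasting-induced genes moved apart: relative to the higher control G6pc lay at -1.07 and Igfbp1 at -0.03, while Cpt1a lay at 0.56 and Angptl4 at 1.21, the last pair having been added after the first pair had been seen. The controls' list medians differed by 0.0263, which leaves the spread between RNAs open for the reason given for Dbp. An effect of the oils themselves stays open.

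For the tissue comparison, 1 of 100 drawn splits of the RNAs, the real one, gave as many calls as the 3313 observed, and the highest of the others was 1. Every other split mixes the tissues within a group and puts their difference into the error, so few calls were bound to follow. The splits therefore do not by themselves exclude chance, and they do not separate tissue from the title tag or the Gapdh ratio.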

How the results depend on the processing

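Chip A alone and hippocampus arrays against the mean of the other arrays were chosen only after the results were seen. The number of liver calls, 0 for each contrast, depended on the filter on dim probe sets. Without it limma called 328 probe sets for fungal oil, 395 for fish oil, 341 for both oils, 609 for fungal against fish oil and 821 for the interaction, where controls both at the floor leave almost no spread by construction. The subset at or above the 75th percentile of brightness gave 26, 39, 37, 7 and 1. The additive fit gave 5 for fungal oil and 16 for both oils, and without either control 5 to 11 for fungal oil, 0 to 4 for fish oil and 5 to 16 for both oils. Counts of at least 2-fold in liver, for fungal oil, fish oil, both oils and the control pair, were 364, 411, 424 and 433 with 2.5 times the floor, 1171, 1386, 1274 and 1457 without the filter, 96, 103, 113 and 72 in the bright subset and 181, 216, 153 and 174 on chip A alone. Hippocampus counts were 1020, 1011 and 498 without the filter and 35, 42 and 21 in the bright subset, and the tissue count was 1770 there. Fewer or more probe sets enter under these filters by construction.

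Quantile normalization and 0.5 times the floor left all 15 counts they were run on within 1.5 times. For the brain fatty acid binding list in liver with fish oil, the test turned direction on chip A alone while the median stayed 0.0381, and the median turned without 1 control (-0.0922 to 0.10). With both oils that list's median lost its sign without 1 control (-0.10 to 0). Directions also turned for the median of the lipoprotein list with both oils (-0.00613 to 0.0993, and -0.11 on chip A alone), for Dbp with fish oil (-0.0165 to 0.10), for Thrsp with fungal oil in the additive fit (-0.13) and for the hippocampus connective tissue list with fish oil against the mean of the other arrays (-0.10); the cause was not tested. Of the 21 called liver lists, chip A alone ended 4 of the 20 it was run on (1 by turning direction), quantile normalization 2 and the mean over probe sets 1. The estimated correlation ended all 21, which says nothing of any list, since it also recovered 0 shifted lists in simulation. The 117 results of named liver genes, counted per gene and contrast, kept their direction under quantile normalization, either other floor and no trend. None could change side of the threshold there, since limma called 0 probe sets in each of these settings. Under other settings some came to pass: 47 in the bright subset while 55 did not, 13 with the additive fit while 89 did not, and 9 without the filter while 108 did not. No paired analysis was possible because the oil groups have 1 RNA each, so that the groups compared share fewer than 2 replicate numbers; the tissue comparison alone could be blocked, by diet, and was fitted so.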

Other observations

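The tests in this part are lists fixed before the data were examined, and none was chosen after the result was seen apart from 1 reference named so. Genes of eicosanoid metabolism, which act on arachidonate and its products, did not pass as a list in liver, with medians of 0.13, 0.24 and -0.21 for fungal oil, fish oil and both oils (camera, adjusted p = 0.508, 0.469 and 0.821). Ephx2, the soluble epoxide hydrolase, read 1139 and 1327 in the controls and 1338, 1654 and 1380 in the oil RNAs. In the hippocampus the same list had medians of 0.07 and 0.13 with the single oils, at percentiles of 70.3 and 82.5, although Ptgds read 3118 and 1843 against 624.

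Stress-related groups also did not pass in liver. Heat shock and chaperone genes had medians of -0.04, -0.03 and 0.02 (adjusted p = 0.395, 0.619 and 0.563), antioxidant and metallothionein genes 0.06, 0.18 and 0.11 (adjusted p = 0.508, 0.350 and 0.821), and acute phase genes 0.10, 0.11 and 0.10 (adjusted p = 0.939, 0.865 and 0.922). In the hippocampus acute phase genes had a median of 0.57 with fish oil (99.4th percentile), with 3 of 5 above the control and 2 below and a mean of 0.16 (median 0.34 against the mean of the other arrays, a reference chosen after seeing the data), and Cp, the copper carrier ceruloplasmin, read 88 in the control and 131 with fish oil. Gluconeogenesis and amino acid genes had a median of 0.42 with fungal oil there (99.1th percentile), with 3 of 5 above the control.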
